A study of Mus musculus with 12 samples.

How the data were processed

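Abdominal fat RNA was measured in 12 mice of the strain BKS.Cg-Dock7m +/+ Leprdb/J, which lack a working leptin receptor and are obese and diabetic. Per the labels, mice aged 12 weeks received adenovirus coding for short hairpin RNAs (shRNAs), and tissue was frozen 1 week later. Each of 4 groups held 7 animals, of which 3 that the labels call representative were put on arrays, so the choice of animals was not random. Every animal received the same total amount of virus. Controls received 4e9 plaque-forming units of control shRNA virus, the LCN13 and TSC22D4 groups received 2e9 of that virus plus 2e9 of the control virus, and the combined group received 2e9 of each gene-directed virus and no control virus. The labels describe separate animals, so the spread between arrays includes that between animals.

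Biotin-labelled cDNA was prepared by the Affymetrix protocol, per the labels. The authors deposited 1 value per probe set and array on a log2 scale, made with RMA (background correction, normalization and summary of the probes of each probe set) per the submitters' processing notes. The RMA version, its settings, the probe set definitions and the genome build are not given in the sources used here. The values ran from 5.62 to 14.4 with a median of 6.31. Sorted columns differed by at most 0.00188, so the arrays had been brought to one common distribution, which removes any change shared by most genes and compresses differences near the lower end. Control replicate 1 was deposited with more decimals than the other arrays, whose values are whole steps of 1 in 1024. Pearson correlations across probe sets lay between 0.994 and 0.998 for pairs of arrays within a group. The number of arrays limits the precision.

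The table held 25206 probe sets. Of these, 23185 were paired with 1 gene symbol, 0 with several and 2021 with none, and the 23185 named ones, each a different gene, were tested. Symbols were looked up in a reference gene table of the mouse assembly GRCm38.p6, which was used for names alone. Lcn13 is listed there as Obp2a. Members of families with similar sequences (Oas, Ifi200, Slfn, Trim30 and immunoglobulin variable genes) may share probe signal, so single members of these families are uncertain.

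Gene tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings) over all 12 arrays with 1 mean per group, which share 1 estimate of the spread per gene. The median residual SD was 0.0647, with 8 residual and 1.38 prior degrees of freedom. Calls were two-sided at a Benjamini-Hochberg adjusted p under 0.05, computed over all genes tested within each comparison. Comparisons were each shRNA group against control, the combined group against each single shRNA group, the interaction (the TSC22D4 effect in the presence of the LCN13 shRNA minus that in its absence), the TSC22D4 and LCN13 effects averaged over the other shRNA, and a moderated F test over the 4 groups. No filter on dim probe sets was applied. All adjusted p-values of genes below are limma's.

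The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, except where an addition is named. In each comparison the rule took the 10 genes with the largest log2 change in each direction among those that passed and whose 3 arrays of one group lay beyond all 3 of the other, which chance alone gives for 10% of genes. For the averaged effects all 6 arrays with the shRNA had to lie beyond the 6 without, which left out some larger changes, and for the interaction no such condition applied. Where fewer passed, all were taken, and where none passed, the 5 with the smallest unadjusted p. Predicted genes, RNA genes and chemosensory receptors were not named by rank. Also named were up to 4 members of each called list, up to 2 members of other lists, the shRNA targets, and 16 fixed readouts: Adipoq, Lep, Pparg, Slc2a4, Irs1, Irs2, Fasn, Scd1, Srebf1, Pck1, Pnpla2, Ucp1, Adgre1, Tnf, Ccl2 and Saa3.

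In all, 41 gene lists with 762 genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. Process lists were de novo lipogenesis, triglyceride synthesis and storage, lipolysis, insulin signalling and glucose uptake, adipocyte identity and adipokines, brown and beige adipocyte genes, fatty acid oxidation, mitochondrial oxidative phosphorylation, tricarboxylic acid cycle, glycolysis, branched-chain amino acid catabolism, cholesterol synthesis and SREBP2 targets, unfolded protein response, heat shock response, interferon-stimulated genes, chemokines and inflammatory cytokines, acute phase genes of fat, immediate early genes, circadian clock genes, glucocorticoid targets, hypoxia response, cell cycle genes, extracellular matrix and fibrosis, cytosolic ribosomal proteins, the TSC22 family and the lipocalin family. Marker lists covered macrophages, T and NK cells, B and plasma cells, neutrophils, mast cells, endothelium, fibroblasts and preadipocytes, mesothelium, red blood cells, liver, skeletal muscle, testis and epididymis, pancreas, intestine and sex-linked genes. For each list, calls were also counted with p-values adjusted over the list alone. Of the 44 list calls in the 5 comparisons fixed for lists, 4 held with an estimated correlation in camera, all of them the interferon-stimulated genes, and 5 held with fry, limma's rotation test of a list by itself.

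Alternatives were eBayes with trend and robust settings, quantile normalization, removal of genes below the 50th or 30th percentile of mean level, array weights, the mean of the probe sets of a gene, an adjusted p under 0.10, fits of only the 6 arrays compared, each array left out in turn, and, for lists, an estimated correlation and fry. Added after the data were seen were the fit of all probe sets, fits without LCN13 replicates 5 and 6, the comparison of the TSC22D4 with the LCN13 group, list tests in that comparison and in the combined group against the LCN13 group, and regroupings that keep the control arrays together. List means per array were compared with exact two-sided permutation tests, 15 in all, adjusted together.

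The gene test was tested on simulated data for TSC22D4 shRNA against control, with 23185 genes, 5 simulations and 200 changed genes in each. It recovered 57.2% of genes changed by 0.25 log2, 90.8% at 0.5, 99.2% at 1 and 99.6% at 2, with a mean of 11 false calls and 0 calls in an unchanged comparison. The changed genes were drawn from all genes, dim ones included. The median SD was 0.0647 over all genes and 0.104 above the 50th percentile of mean level, so recovery of brighter genes may be lower. On simulated data with 41 lists, camera called the 1 changed list and 0 of the others. The simulated genes varied independently of each other, so this could not test false calls of lists whose genes move together. Probe sets without a gene symbol here were left out of the counts. Liver and muscle of these animals were not analysed here.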

Results

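RNA levels were compared in abdominal fat of obese diabetic db/db mice. They had received control, LCN13, TSC22D4 or combined LCN13 and TSC22D4 shRNA adenovirus 1 week earlier, with 3 arrays per group. TSC22D4 is a protein of the TGF-beta-stimulated clone 22 family, and LCN13 is a secreted lipocalin. The series title places the study in work on TSC22D4, high blood glucose and insulin resistance. The design asks how fat RNA differs with each shRNA virus and whether the difference with the TSC22D4 shRNA depends on the LCN13 shRNA.

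The targeted genes were examined first. Tsc22d4 lay between 7.56 and 7.88 log2 over the 12 arrays. Group means were 7.68 in control, 7.67 in LCN13, 7.67 in TSC22D4 and 7.61 in the combined group (n = 3 each). Its log2 change was -0.0074 (SE 0.08, limma adjusted p = 0.989) with TSC22D4 shRNA and -0.07 (adjusted p = 0.888) with both. Lcn13, listed as Obp2a, lay between 5.71 and 5.79, near the lower end of the arrays. Its log2 change was -0.01 (adjusted p = 0.858) with LCN13 shRNA and -0.0085 (adjusted p = 0.967) with both. No lower level of either target was detectable in fat. The labels do not name the tissue that the virus reached, and a probe set this dim cannot check the LCN13 groups.

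TSC22D4 shRNA against control asked how fat differed with that virus. This group also received less control virus than the controls. A gain of shRNA virus and a loss of control virus therefore cannot be told apart in any comparison with control. Interferon-stimulated genes were lower than in control: of 28 measured, 25 passed lower and 0 higher, 27 lower when adjusted over the list alone. Their median log2 change was -1.68 (camera adjusted p = 2e-71, adjusted p = 0.00948 with an estimated correlation). Oas1g, of the oligoadenylate synthetase family that senses double-stranded RNA, fell by 3.50 log2 (SE 0.17, adjusted p = 7.4e-06), from 10.14 to 6.64. Ifit1, which binds viral RNA, fell by 3.25 (SE 0.13, adjusted p = 4.71e-06), and the transcription factor Irf7 fell by 2.60, from 12.52 to 9.92. The other largest decreases were Oas3 (-3.48), Ifi213 (-3.29), Usp18 (-3.00), Slfn4 (-2.94), Slfn1 (-2.79), Ifi209 (-2.61) and Dhx58 (-2.60). The list does not hold Oas1g, Ifi213, Slfn4, Slfn1 or Ifi209, nor Trim30a and Trim30d named below. The Fc receptor Fcgr1 (-1.56, adjusted p = 0.0108) and the chemokine Cxcl10 (-1.09, adjusted p = 0.0409) also fell. Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell by 0.82 (SE 0.14, adjusted p = 0.0243). Smaller decreases were those of the fatty acid transporter Slc27a1 (-0.39, adjusted p = 0.00151), Nampt (-0.33, adjusted p = 0.0365) and Gzmb (-0.33, adjusted p = 0.0401). Slc27a1 was named in this comparison after its value was seen. Leaving out 1 array at a time ended the calls of Cxcl10 (10 of 12 fits, adjusted p up to 0.149), Gzmb (10, up to 0.139), Nampt (9, up to 0.137), Pdk4 (5, up to 0.0976, control replicates 1 and 3 and each TSC22D4 array) and Slfn4 (4, up to 0.0818, control replicate 3 and each TSC22D4 array).

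With TSC22D4 shRNA Angptl8, a secreted inhibitor of lipoprotein lipase activity that is induced by feeding, rose by 1.70 log2 (SE 0.26, adjusted p = 0.0155), from 9.03 to 10.73. Srebf1, which codes for the lipogenic transcription factor SREBP1, rose by 0.47 (SE 0.08, adjusted p = 0.022), and Lpin1, a phosphatidate phosphatase, by 0.44 (SE 0.08, adjusted p = 0.0415). Of 19 de novo lipogenesis genes 1 passed higher and 0 lower, 12 higher and 1 lower when adjusted over the list alone. Their median was 0.36 (camera adjusted p = 1.12e-07, adjusted p = 0.564 with an estimated correlation). Members that did not pass included Elovl6 (0.98, adjusted p = 0.221), Acaca (0.65, adjusted p = 0.116), Acss2 (0.58, adjusted p = 0.282) and Pnpla3 (0.52, adjusted p = 0.157). Cholesterol synthesis genes had a median of 0.22 over 20 members (camera adjusted p = 6.07e-06, adjusted p = 0.881 with an estimated correlation). Of these 0 passed by limma, 7 were higher when adjusted over the list alone, and Dhcr7 was at 0.61, Lss at 0.55, Pmvk at 0.46 and Nsdhl at 0.42. Triglyceride synthesis and storage had a median of 0.07 over 19 genes (camera adjusted p = 0.0231, adjusted p = 0.881 with an estimated correlation). Lpin1 passed higher and Slc27a1 lower, and 4 were higher and 1 lower when adjusted over the list alone. Gpam at 0.49, Gpd1 at 0.31 and Agpat2 at 0.29 did not pass. Without 1 array, Lpin1 lost its call in 10 of 12 fits (adjusted p up to 0.144), Srebf1 in 5 (up to 0.0788, control replicates 1 and 3 and each TSC22D4 array) and Angptl8 in 2 (up to 0.0761, TSC22D4 replicates 10 and 11).

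The single genes Igkv4-70 (2.04, SE 0.33, adjusted p = 0.0184), Igkv5-43 (1.74) and Igkv4-73 (1.41) rose with TSC22D4 shRNA. Their calls were lost in 4, 10 and 4 of 12 fits without 1 array, with an adjusted p of up to 0.0826, 0.146 and 0.0687, among them those without control replicate 2 or 3 or TSC22D4 replicate 10 or 12. Other leading increases were the oxidized-LDL receptor Olr1 (1.03, SE 0.13, adjusted p = 0.00517) and the dendritic cell lectin Cd209a (1.02, SE 0.12, adjusted p = 0.00288). Tuba1a (0.80), Gfra2 (0.68), Krt222 (0.67) and the growth factor Nrg4 (0.59, adjusted p = 0.0409) followed, of which Gfra2 lost its call in 10 such fits (adjusted p up to 0.164), Nrg4 in 9 (up to 0.144) and Tuba1a in 7 (up to 0.110). B and plasma cell markers had a median of 0.05 (15 genes, camera adjusted p = 0.0481, adjusted p = 0.881 with an estimated correlation), with Jchain at 1.47 (adjusted p = 0.226). Their mean, relative to the 12-array mean, was 0.27, -0.07 and 0.12 in TSC22D4 replicates 10, 11 and 12. Extracellular matrix genes had a median of 0.14 (26 genes, camera adjusted p = 0.0191, adjusted p = 0.881 with an estimated correlation), with Col15a1 at 0.45 and the matrix glycoprotein gene Thbs2, named after its value was seen, falling (-0.66, adjusted p = 0.0314, lost in 8 fits without 1 array, up to 0.118). Oxidative phosphorylation (40 genes, median 0.07, camera adjusted p = 0.00562, adjusted p = 0.881 with an estimated correlation) and branched-chain amino acid catabolism (18 genes, median 0.04, camera adjusted p = 0.0499, adjusted p = 0.898 with an estimated correlation) had small upward shifts. Immediate early genes had a downward shift (20 genes, median -0.09, camera adjusted p = 0.0481, adjusted p = 0.881 with an estimated correlation), with Dusp1 at -0.38. Adjusted over the list alone, immediate early genes had 3 lower, extracellular matrix 2 higher and 2 lower, and the other lists of this group 0.

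In total 272 of 23185 genes passed with TSC22D4 shRNA, 68 higher and 204 lower, of which 6 and 70 changed at least 2-fold. Of the 16 readouts only Srebf1 passed. The others ran from -0.43 for Pck1 (adjusted p = 0.64) to 1.13 for Saa3 (adjusted p = 0.173), with Fasn at 0.48 (adjusted p = 0.147) and Adipoq at -0.08. The count was 447 with array weights, 142 when only the 6 arrays were fitted, and 156 and 153 without TSC22D4 replicates 10 and 11.

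**Figure D1:**
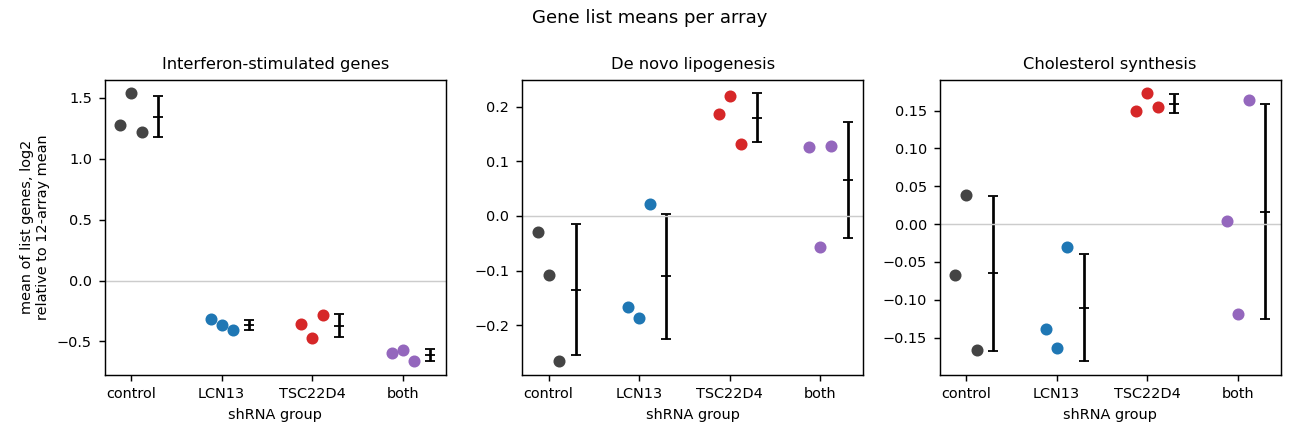
Mean log2 level of interferon-stimulated, de novo lipogenesis and cholesterol synthesis genes in each of the 12 arrays, relative to the mean of all arrays (y axis, log2), by group (x axis); dots are arrays, and bars give the group mean with its SD (n = 3). The control arrays lie at 1.22 to 1.54 for interferon-stimulated genes and all other arrays below 0, and the TSC22D4 arrays lie at 0.13 to 0.22 for de novo lipogenesis.

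LCN13 shRNA against control asked the same of the lipocalin. The control arrays were the same, and this group too received less control virus than the controls. Interferon-stimulated genes were lower here too. Of 28 measured, 25 passed lower and 0 higher, and all 28 were lower when adjusted over the list alone. The median was -1.77 (camera adjusted p = 1.25e-74, adjusted p = 0.00815 with an estimated correlation). Oas1g fell by 3.73 log2 (SE 0.17, adjusted p = 8.17e-06), followed by Oas3 (-3.50), Ifi213 (-3.32), Ifi209 (-3.11), Ifit1 (-3.00), Slfn4 (-2.94), Usp18 (-2.90), Slfn1 (-2.70), Trim30a (-2.47) and Irf7 (-2.43). Metabolic genes that fell were Pdk4 (-0.78, adjusted p = 0.0269), the acetyl-CoA carboxylase Acacb (-0.70, SE 0.13, adjusted p = 0.0325), Nampt (-0.45, adjusted p = 0.00636) and Slc27a1 (-0.35, adjusted p = 0.00285). Increases were led by Cd209a (0.64, SE 0.12, adjusted p = 0.0353) and the microtubule protein Map1b (0.63, SE 0.11, adjusted p = 0.0276). Aldh1a3 (0.50), Pfn2 (0.50), the podocalyxin gene Podxl (0.49, adjusted p = 0.00872), Gxylt2 (0.48), Ltbp4 (0.45), Dusp14 (0.45), Tatdn1 (0.44) and the cystine transporter Slc7a11 (0.39, adjusted p = 0.0197) rose as well. De novo lipogenesis genes had a median of 0.0012 (camera adjusted p = 0.947). Leaving out 1 array at a time ended the calls of Aldh1a3 (10 of 12 fits, adjusted p up to 0.135), Acacb (9, up to 0.107), Cd209a (9, up to 0.127), Dusp14 (6, up to 0.107), Tatdn1 (6, up to 0.106), Pdk4 (5, up to 0.0867) and Map1b (4, up to 0.108, control replicates 1 and 2, LCN13 replicates 5 and 6). Pfn2 (up to 0.0891) and Ltbp4 (up to 0.0664) lost theirs without control replicate 2 or LCN13 replicate 5 or 6, Slc7a11 (up to 0.0851) without either of the last, and Slfn4 (up to 0.0722) without any LCN13 array.

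Marker lists were tested in the LCN13 group too. Mesothelial markers, from the cell layer that covers abdominal organs, had a median of 0.41 over 15 genes (camera adjusted p = 0.00188, adjusted p = 0.871 with an estimated correlation). Of these 0 passed by limma and 2 were higher when adjusted over the list alone, with Gpm6a at 0.93, Rspo1 at 0.91 (adjusted p = 0.0829), Upk1b at 0.66 and Upk3b at 0.61. All 15 lay above the median of the 9 arrays of other groups in LCN13 replicates 5 and 6, against 4 in replicate 8. Liver markers were high on the same arrays, at 0.24, 0.23 and -0.03 relative to the 12-array mean (20 genes, median 0.09, camera adjusted p = 0.00627, adjusted p = 0.871 with an estimated correlation), with Alb at 1.83 (SE 0.83, adjusted p = 0.408). The highest liver marker mean in the combined group was 0.26, so high values were not confined to these arrays. Fibroblast and preadipocyte markers had a median of 0.11 (14 genes, 1 higher when adjusted over the list alone, camera adjusted p = 0.0103, adjusted p = 0.871 with an estimated correlation), with Dpp4 at 0.41 (adjusted p = 0.0905), Cd55 at 0.38 and Lum at 0.30. T and NK cell markers had a median of -0.05 (21 genes, 3 lower when adjusted over the list alone, camera adjusted p = 0.00302, adjusted p = 0.871 with an estimated correlation), with Gzmb falling (-0.43, adjusted p = 0.00851) and Nkg7 at -0.72. Chemokines had a median of -0.08 (24 genes, 3 lower when adjusted over the list alone, camera adjusted p = 0.00405, adjusted p = 0.871 with an estimated correlation), with Cxcl10 at -0.88 (adjusted p = 0.0873). Macrophage markers had a median of -0.09 (22 genes, camera adjusted p = 0.0244), with Fcgr1 falling (-1.84, adjusted p = 0.00353), and cell cycle genes a median of -0.10 (25 genes, camera adjusted p = 0.00381), both with adjusted p = 0.871 with an estimated correlation. Fatty acid oxidation (18 genes, median -0.08, camera adjusted p = 0.0194, adjusted p = 0.871 with an estimated correlation) and brown and beige adipocyte genes (15 genes, median -0.05, 1 lower when adjusted over the list alone, camera adjusted p = 0.0244, adjusted p = 0.385 with an estimated correlation) were also called lower. Ehhadh was at -0.42, Cox8b at -0.34 and Ppargc1b at -0.32 (adjusted p = 0.0711). Without LCN13 replicates 5 and 6, the mesothelial median was -0.13 (adjusted p = 0.512) and that of fatty acid oxidation 0.05 (adjusted p = 0.357). Liver markers (0.0093, adjusted p = 0.746), brown and beige genes (-0.02, adjusted p = 0.383) and cell cycle genes (-0.08, adjusted p = 0.191) lost their calls too, and 5 of the 10 lists kept theirs.

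With LCN13 shRNA 333 genes passed, 92 higher and 241 lower, of which 0 and 78 changed at least 2-fold. Of the 16 readouts 0 passed under limma, with values from -0.22 for Slc2a4 to 0.54 for Pck1 (adjusted p = 0.487). The count was 680 with array weights and 102 when only the 6 arrays were fitted. It was 211, 205 and 209 without control replicate 2, LCN13 replicate 5 and LCN13 replicate 6, and 100 without both of the last, an alternative added after the data were seen.

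**Figure D2:**
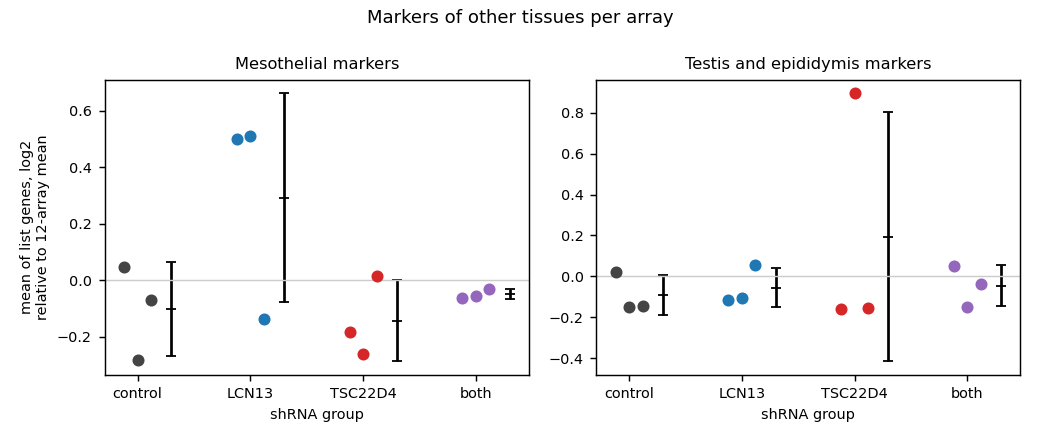
Mean log2 level of mesothelial markers and of testis and epididymis markers in each of the 12 arrays, relative to the mean of all arrays (y axis, log2), by group (x axis); dots are arrays, and bars give the group mean with its SD (n = 3). Mesothelial markers lie at 0.50 and 0.51 in LCN13 replicates 5 and 6, and testis and epididymis markers at 0.90 in TSC22D4 replicate 11.

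The combined group received no control virus and was set against the same control arrays. Interferon-stimulated genes were also lower with both shRNAs than in control. Their median was -1.85, with 25 of 28 lower, 27 when adjusted over the list alone (camera adjusted p = 5.46e-86, adjusted p = 0.00497 with an estimated correlation). Oas1g fell by 3.76 (adjusted p = 3.43e-06) and Irf7 fell by 3.25 (SE 0.13, adjusted p = 1.94e-06). The other largest decreases were Ifit1 (-3.64), Oas3 (-3.56), Usp18 (-3.53), Ifi213 (-3.40), Slfn4 (-3.11), Slfn1 (-2.96), Rtp4 (-2.93) and Ifi209 (-2.85). Chemokines had a median of -0.10 (24 genes, 1 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.000703, adjusted p = 0.70 with an estimated correlation). Cxcl10 fell by 1.36 (adjusted p = 0.0117), and the monocyte chemokines lay lower without passing, Ccl3 at -1.01 (adjusted p = 0.076), Ccl7 at -0.84 (adjusted p = 0.0532) and Ccl8 at -0.62. Macrophage markers had a median of -0.09 (camera adjusted p = 0.0355, adjusted p = 0.937 with an estimated correlation), with Fcgr1 falling (-1.95, adjusted p = 0.0023). Hdc (-0.55), Nampt (-0.40), Gzmb (-0.39) and Slc27a1 (-0.37, adjusted p = 0.00169) fell too. Calls were lost without 1 array for Hdc (8 of 12 fits, adjusted p up to 0.121), Slfn4 (up to 0.0649, each array of the combined group), Gzmb (up to 0.0719, control replicate 2 and combined-group replicates 13 and 16), Cxcl10 (up to 0.0597, control replicate 2 and combined-group replicate 13) and Nampt (up to 0.057, control replicate 2 and combined-group replicate 16).

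Increases with both shRNAs were led by Tuba1a (0.89, SE 0.14, adjusted p = 0.0168), Olr1 (0.79, adjusted p = 0.0212), and Cd209a (0.75, adjusted p = 0.0157). Rasd1 (0.68), Dzip3 (0.49), Krt222 (0.48), Lyplal1 (0.44), Snai2 (0.44), Tatdn1 (0.43) and Kank1 (0.42, adjusted p = 0.00427) rose too, and the endoplasmic reticulum chaperone Dnajb9 rose by 0.33 (adjusted p = 0.0013). Without 1 array, calls were lost for Krt222 (10 of 12 fits, adjusted p up to 0.167), Lyplal1 (10, up to 0.130), Rasd1 (10, up to 0.134), Snai2 (9, up to 0.138), Tatdn1 (7, up to 0.0746), Dzip3 (6, up to 0.0876, each control and combined-group array), Tuba1a (5, up to 0.0673), Olr1 (4, up to 0.0748) and Cd209a (3, up to 0.0636). De novo lipogenesis genes had a median of 0.18, 0 passing over all genes or over the list alone (camera adjusted p = 0.00104, adjusted p = 0.721 with an estimated correlation), with Elovl6 at 0.74 and Acaca at 0.40. Red blood cell markers were at 0.80, 0.56 and 0.67 in the 3 arrays, relative to the 12-array mean, against 0.29, -0.45 and -0.95 in the controls. Their median log2 change was 1.10 (5 genes, 2 higher when adjusted over the list alone, camera adjusted p = 0.0154, adjusted p = 0.742 with an estimated correlation), with Hbb-b1 at 2.52 (SE 0.84, adjusted p = 0.258) and Alas2 at 1.54. Immediate early genes had a median of -0.14 (5 lower when adjusted over the list alone, camera adjusted p = 0.0033, adjusted p = 0.721 with an estimated correlation), with Dusp1 at -0.45. Fibroblast markers had a median of 0.07 (3 higher when adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.862 with an estimated correlation), with Lum at 0.53 (adjusted p = 0.0546), and branched-chain amino acid catabolism one of 0.05 (camera adjusted p = 0.0466, adjusted p = 0.937 with an estimated correlation), with Dld at 0.32. In this comparison 311 genes passed, 73 higher and 238 lower, of which 0 and 87 changed at least 2-fold. Of the 16 readouts 0 passed under limma, with values from -0.61 for Ccl2 (adjusted p = 0.245) to 0.72 for Irs2 (adjusted p = 0.267). The count was 518 with array weights, 126 when only the 6 arrays were fitted, and 165 and 199 without replicates 13 and 14 of the combined group.

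The 3 comparisons shared the 3 control arrays, and 151 genes were lower in all 3, 25 of them on the interferon list. Higher in all 3 were 7 genes, Gm14295, Sdc2, Cd209a, Usp34, Rab10, Tmem184c and Aff4, named here after their values were seen. For TSC22D4 and LCN13 shRNA 154 lower calls were shared where independent lists would share 2.12, and 8 higher calls where they would share 0.270. Log2 changes across genes correlated with Pearson r = 0.518, against 0.499 in 100 simulations of unchanged groups with the same controls, and r was 0.444 without the interferon list. They had the same sign in 57.0% of genes against 66.6% simulated. The covariance was 0.0169, or 0.0125 without that list, against 0.00432 simulated. TSC22D4 and the combined group had r = 0.789 (0.754 without that list) against 0.50, a covariance of 0.0258 against 0.00434, and the same sign in 69.5% of genes against 66.6%. They shared 169 lower and 16 higher calls against 2.09 and 0.214. LCN13 and the combined group had r = 0.727 (0.676 without that list) against 0.501, a covariance of 0.0222 against 0.00434, and the same sign in 65.3% against 66.6%. They shared 180 lower and 17 higher calls against 2.47 and 0.290. Genes are not independent replicates, and part of the excess may come from the shared controls, which were not split between the comparisons. The simulations shared the controls but drew each gene independently, and the shared calls were set only against independent lists.

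With the LCN13 shRNA added to the TSC22D4 shRNA, at the same total virus, 0 genes passed by limma, where 1602 had an unadjusted p under 0.05 and 1159 are expected by chance. The smallest p-values, all with an adjusted p of 0.366, belonged to Rtp4 (-0.72), Fam110c (-0.43), Szrd1 (-0.29), Rab11b (-0.28) and Kptn (-0.21) on the lower side and to Setd6 (0.34), Dnajc10 (0.22), Cmtm4 (0.22), Gabpa (0.19) and AI854703 (0.14) on the higher. Interferon-stimulated genes lay further down by a median of -0.20, with 8 lower when adjusted over the list alone (camera adjusted p = 4.35e-12, adjusted p = 0.564 with an estimated correlation). Irf7 was at -0.65, Oas2 at -0.61 and Usp18 at -0.53. Lists called lower, each with its median and camera adjusted p, were cholesterol synthesis (-0.17, 0.000416), B and plasma cell markers (-0.07, 0.000666), cell cycle (-0.09, 0.000996), chemokines (-0.05, 0.00159) and de novo lipogenesis (-0.14, 0.0039). The others, given likewise, were oxidative phosphorylation (-0.03, 0.0039), neutrophil markers (-0.04, 0.0039), acute phase genes (-0.10, 0.00657), T and NK cell markers (-0.06, 0.0129) and glycolysis (-0.07, 0.0167). Red blood cell markers had a higher median (0.73, camera adjusted p = 0.00292). Adjusted over the list alone, red blood cell markers had 2 higher and neutrophil markers and glycolysis 1 lower each, and the other lists 0. With an estimated correlation the lowest of these was adjusted p = 0.564, so 0 lists held. The gene count was 1 without TSC22D4 replicate 11 and 4 without replicate 16 of the combined group.

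With the TSC22D4 shRNA added to the LCN13 shRNA, again in place of the control virus, 2 genes passed by limma, where 2477 had an unadjusted p under 0.05. Here too the gain of the shRNA virus and the loss of the control virus cannot be told apart. Dnajb9 rose by 0.36 (SE 0.04, adjusted p = 0.0445), and Samd9l, an interferon-inducible antiviral gene, fell by 0.37 (SE 0.04, adjusted p = 0.0445), from 8.98 to 8.61. They lost their calls in 7 and 8 of 12 fits without 1 array (adjusted p up to 0.308). Irf7 was at -0.82 (adjusted p = 0.109) and Rtp4 at -0.73. In list tests added after the data were seen, camera called 10 lists, 7 higher and 3 lower, and 0 lists held with an estimated correlation or with fry. Interferon-stimulated genes had a median of -0.21, with 0 passing and 12 lower when adjusted over the list alone (camera adjusted p = 8.67e-08, adjusted p = 0.747 with an estimated correlation). De novo lipogenesis had a median of 0.21 (camera adjusted p = 0.00104, adjusted p = 0.747 with an estimated correlation). The other 8, each with its median and camera adjusted p, were fatty acid oxidation (0.11, 0.00104), branched-chain amino acid catabolism (0.07, 0.0232), cholesterol synthesis (0.10, 0.014), cell cycle (0.07, 0.0293), red blood cell markers (1.25, 0.00233) and sex-linked genes (0.12, 0.0272) on the higher side and mesothelial (-0.35, 0.00104) and liver markers (-0.05, 0.0293) on the lower. With an estimated correlation the lowest of these was adjusted p = 0.671. Adjusted over the list alone, red blood cell markers had 3 higher, fatty acid oxidation 1 higher and mesothelial markers 3 lower, and the other 5 lists 0. Single members that did not pass were Hbb-b1 at 2.34, Slc4a1 at 1.25, Alb at -1.34, Krt8 at -0.83 and Rspo1 at -0.80. The count of genes depended on every array. It was 0 by limma without control replicate 2, LCN13 replicate 5 or 6, TSC22D4 replicate 11 or combined-group replicate 13 or 14. It was 1 without control replicate 1, TSC22D4 replicate 10 or combined-group replicate 16, 4 without TSC22D4 replicate 12, 11 without control replicate 3 and 94 without LCN13 replicate 8. It was 14 with array weights, 8 with trend and robust settings, 7 and 4 above the 50th and 30th percentiles, and 0 by limma when only the 6 arrays were fitted or without both LCN13 replicates 5 and 6.

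The interaction asked whether the effect of both shRNAs differed from the sum of each. Interferon-stimulated genes had a median interaction of 1.53, with 19 of 28 passing positive and 0 negative, 27 when adjusted over the list alone (camera adjusted p = 6.88e-70, adjusted p = 0.0102 with an estimated correlation). Oas1g had means of 10.14 in control, 6.41 with LCN13, 6.64 with TSC22D4 and 6.38 with both, an interaction of 3.46, since a gene about equally lower in all 3 groups has a positive interaction. Oas3 (3.41), Ifi213 (3.21), Ifi209 (2.86), Ifit1 (2.61), Slfn1 (2.54), Usp18 (2.37), Trim30d (2.33), Trim30a (2.30) and Ifit2 (2.25) followed. With LCN13, TSC22D4 and both, Oas3 was at 6.40, 6.42 and 6.34, like Oas1g near the array median of 6.31. A further fall with both could hardly show at that level, so a positive interaction of these genes says little. Ifit1 lay above that level, at 8.70, 8.45 and 8.06. Pdk4 had another form: it was at 11.4 in control and 11.2 with both, and at 10.6 with either alone, an interaction of 1.45 (SE 0.20, adjusted p = 0.0148). Negative interactions were found for the ribosome assembly gene Mrto4 (-0.61, adjusted p = 0.0387), Podxl (-0.60), Rab11b (-0.47), the muscle filament gene Des (-0.45), Plec (-0.40), Eif5a (-0.38) and Mrps2 (-0.30). In total 92 genes passed, 85 positive and 7 negative, and 80 of the 85 were lower in all 3 groups against control. The count was 53 without LCN13 replicate 5, 47 and 54 without TSC22D4 replicates 10 and 11, and 60 without combined-group replicate 13. Without 1 array the call was lost for Podxl (11 of 12 fits, adjusted p up to 0.146), Mrps2 (10, up to 0.107), Mrto4 (9, up to 0.121), Eif5a (8, up to 0.0729), Plec (6, up to 0.0660), Des (5, up to 0.0660), Rab11b (4, up to 0.0526), Pdk4 (up to 0.0535, TSC22D4 replicates 10 and 11 and combined-group replicate 14) and Trim30d (up to 0.0517, LCN13 replicate 5).

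Averaged over the LCN13 shRNA, Gys2, the liver form of glycogen synthase, was higher with TSC22D4 shRNA by 1.31 (SE 0.20, adjusted p = 0.0158), with means of 8.40 in control, 7.96 with LCN13, 9.69 with TSC22D4 and 9.29 with both. Olr1 (0.94, adjusted p = 0.00131), Tuba1a (0.67), Fap (0.61, adjusted p = 0.025), AF357425 (0.60), the sterol synthesis enzyme Lss (0.53, adjusted p = 0.025), H3c14 (0.51), Tmem64 (0.45), Krt222 (0.45) and Chid1 (0.45) also rose. In all 23 genes were at least 2-fold lower, and larger decreases than those given here were left out by the naming rule, which asks that the 6 arrays with TSC22D4 shRNA all lie below the 6 without. The decreases it took were Phf11d (-1.09), Ifi27l2a (-0.95), Ddx58 (-0.84), Helz2 (-0.79), Adar (-0.77), Lgals9 (-0.77), Samd9l (-0.77, adjusted p = 5.3e-06), Irf9 (-0.64), Plscr2 (-0.61) and Lgals3bp (-0.58). These averages rest on unequal parts: Helz2 was at -1.43 against control but at -0.15 (adjusted p = 0.626) in the combined against the LCN13 group, where Phf11d was at -0.29 (adjusted p = 0.176). Calls were lost without 1 array for Tmem64 (8 of 12 fits, adjusted p up to 0.0641), Fap (7, up to 0.0731), H3c14 (7, up to 0.0740), Lss (7, up to 0.0695), Plscr2 (6, up to 0.0805) and Chid1 (4, up to 0.0638). This averaged effect held 323 genes, 130 higher and 193 lower. The count was 810 with array weights, 132, 155 and 718 without LCN13 replicates 5, 6 and 8, 161, 157 and 186 without TSC22D4 replicates 10, 11 and 12, and 155 and 188 without combined-group replicates 13 and 14.

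Averaged over the TSC22D4 shRNA, 251 genes passed with LCN13 shRNA, 82 higher and 169 lower, of which 0 and 28 changed at least 2-fold. Of the genes whose 6 arrays with LCN13 shRNA all lay below the 6 without, Ifi209 (-1.68), Ms4a6b (-1.26), Epsti1 (-1.02), Gbp10 (-0.81), Ifi35 (-0.69), Bst2 (-0.63), Trim21 (-0.61), Parp11 (-0.60), Aoah (-0.59) and the peptide transporter Tap1 (-0.57) fell. These decreases rest mainly on the difference from control: Ifi209 was at -3.11 and Bst2 at -1.02 there, but both at -0.24 (adjusted p = 0.906 and 0.777) in the combined against the TSC22D4 group, where 0 genes passed by limma. Plekha6 (0.35), Gxylt2 (0.35, adjusted p = 0.0071), Ltbp4 (0.32), Tcf21 (0.27), Zfp808 (0.26), Eml1 (0.24), Ncl (0.24), Anapc10 (0.24), Rabgap1l (0.23) and Smc3 (0.22) rose. Of these Ncl lost its call in each of 12 fits without 1 array (adjusted p up to 0.121), Plekha6 in 11 (up to 0.110), Smc3 in 7 (up to 0.0765), Trim21 in 6 (up to 0.0861), Ltbp4 in 6 (up to 0.0608), Zfp808 in 5 (up to 0.0603), Anapc10 in 3 (up to 0.0572) and Aoah in 2 (up to 0.0549). The count was 614 with array weights, 389 without control replicate 1, 154 without LCN13 replicate 6, 146 and 135 without TSC22D4 replicates 10 and 12, and 151 without combined-group replicate 13. Over the 4 groups, 374 genes differed by the F test. That count was 935 with array weights, 239 without control replicate 2, 209 and 227 without LCN13 replicates 5 and 6, 214 without TSC22D4 replicate 10 and 231 without combined-group replicate 13.

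Of the 41 lists, 19 were called in none of the 5 comparisons fixed for lists. The lowest camera adjusted p over those comparisons was 0.134 for lipolysis, 0.0606 for insulin signalling, 0.33 for adipocyte identity, 0.084 for the tricarboxylic acid cycle, 0.0876 for the unfolded protein response, 0.146 for heat shock, 0.059 for circadian clock genes, 0.163 for glucocorticoid targets, 0.351 for hypoxia, 0.312 for ribosomal proteins, 0.182 for the TSC22 family and 0.0586 for lipocalins. Among marker lists it was 0.0511 for mast cells, 0.427 for endothelium, 0.351 for skeletal muscle, 0.214 for testis and epididymis, 0.655 for pancreas, 0.707 for intestine and 0.0503 for sex-linked genes. Medians against control for these lists ran from -0.10 in the TSC22 family to 0.23 in circadian clock genes.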

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

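The tests of the interferon pattern and the regroupings that keep the control arrays together were chosen after the results were seen, and the counts of other splits of the arrays were planned.

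The interaction, which asks whether the effect of both shRNAs differs from the sum of each, picked out 92 genes and 5 gene lists. It is not a difference between the 2 single effects, and a gene about equally lower in all 3 shRNA groups has a positive interaction. For Oas1g and Oas3 all 3 shRNA groups lay near the array median, where a further fall with both could hardly show. Interferon-stimulated genes had a median interaction of 1.53, red blood cell markers 0.68, B and plasma cell markers -0.0936, glycolysis -0.0454 and oxidative phosphorylation -0.0443, and all but the first had adjusted p = 0.846 with an estimated correlation. Single genes were Oas1g (3.46), Oas3 (3.41), Ifi213 (3.21), Ifi209 (2.86), Ifit1 (2.61), Slfn1 (2.54), Usp18 (2.37), Trim30d (2.33), Trim30a (2.30), Ifit2 (2.25), Mrps2 (-0.30), Eif5a (-0.38), Plec (-0.40), Des (-0.45), Rab11b (-0.47), Podxl (-0.60) and Mrto4 (-0.61). Among probe sets without a gene symbol here, which no comparison above used, 26 of 2021 differed between groups by the F test.

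Interferon-stimulated genes were higher in the 3 control arrays (mean 10.2, SD 0.169) than in the 9 others (mean 8.41), by 1.79 log2 (exact two-sided permutation p = 0.00455, the smallest that 220 arrangements can give, adjusted p = 0.0487), and 26 of 28 members had all 3 control arrays above all others. A larger share of macrophages in the control pieces is argued against, since macrophage markers were higher there by only 0.104 (control mean 10.7, SD 0.168). T and NK cell and neutrophil markers, with control means of 6.87 and 6.22, lay near the array median and could hardly test those cells. Chemokines were higher in control by 0.143 (exact two-sided permutation p = 0.0227, adjusted p = 0.0852). Also argued against is 1 unusual control array, since at least 23 members passed lower in each comparison without any 1 of the controls. The amount of control virus remains a candidate explanation: the combined group, which received none, lay below the 6 single-shRNA arrays by -0.24 (exact two-sided permutation p = 0.0119, adjusted p = 0.0595), lower in 23 of 28 members than in both single groups. The design takes away control virus wherever it adds a gene-directed shRNA, so the same order would also come from an effect of each gene-directed shRNA, which stays open as a biological explanation. The list mean was 10.2 at 4e9 units of control virus, 8.50 at 2e9 and 8.25 without it, and how the animals were selected stays open too. Scan dates are not given in the sources used here, so a batch that follows the groups could not be tested.

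With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 272 genes for TSC22D4, 333 for LCN13 and 311 for both shRNAs against control, and the highest other splits 2, 2 and 0, so 1 split of 10 reached each real count. For the combined group against LCN13 the values were 2 and 0, again 1 split of 10, and against TSC22D4 they were 0 and 0, so all 10 did. Of 100 regroupings of the 12 arrays, 1, the real one, reached each count. This held for the interaction (92 genes, highest other 60), the averaged TSC22D4 effect (323, highest other 58), the averaged LCN13 effect (251, highest other 124) and the F test (374, highest other 144). Each highest other came from the 1 other regrouping that kept the 3 control arrays together, and the 98 that parted them gave at most 2, 1, 7 and 3 genes, so these counts mainly show that the control arrays stand apart. Of 100 regroupings of the 9 other arrays with the control arrays kept together, 27 gave at least as many interaction genes as the 92 found (highest other 241), so control arrays that stand apart may account for that number whatever the grouping of the others. For the averaged TSC22D4 effect, the averaged LCN13 effect and the F test 1 of 100, the real one, reached the count (highest others 179, 241 and 243). Control arrays that stand apart thus did not give these numbers by themselves in the regroupings drawn. For the averaged LCN13 effect the margin was small, with 241 genes against the 251 found.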

How the results depend on the processing

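Fits without LCN13 replicates 5 and 6, the fit of all probe sets and the comparison of TSC22D4 with LCN13 were chosen after seeing the data. Counts below are in the order TSC22D4, LCN13 and both shRNAs against control, unless another is given, and the cause of each change was not tested except that smaller fits hold fewer arrays. Array weights gave 447, 680 and 518 genes, 14 for both against LCN13, 810 and 614 for the averaged TSC22D4 and LCN13 effects and 935 for the F test. An adjusted p under 0.10, a looser threshold, gave 443, 527 and 541, then 11, 788, 516 and 793. Only the 6 arrays compared gave 142, 102, 126 and, for both against LCN13, 0, where trend and robust settings gave 8 and genes above the 50th and 30th percentiles 7 and 4. Without LCN13 replicates 5 and 6, which leaves 1 array assumed to vary like the other groups, LCN13 against control gave 100 and both against LCN13 gave 0, and the list medians of fatty acid oxidation (0.0546) and mesothelial markers (-0.13) turned, while 3 more of the 10 called lists lost their calls and 5 kept them. Lists called were 1, 1 and 1 with an estimated correlation and 1, 2 and 2 with fry, of which sex-linked genes with both shRNAs were not called by camera, and they were 0 and 0 for both against TSC22D4 and 1 and 1 for the interaction. Each of the 12 fits without 1 array left a group with 2 arrays and gave 153 to 350, 205 to 426 and 165 to 376 genes, 0 to 4 for both against TSC22D4, 0 to 94 for both against LCN13, 47 to 104 for the interaction, 132 to 718 and 135 to 389 for the averaged effects, 209 to 531 for the F test and 2 to 582 for TSC22D4 against LCN13. Lists called ran from 3 to 11, 6 to 12 and 4 to 13, 7 to 16 for both against TSC22D4 and 2 to 10 for the interaction. Tsc22d4 ran from -0.06 to 0.09 with TSC22D4 shRNA and from -0.13 to 0.02 with both, and Obp2a from -0.02 to -0.0067 with LCN13 shRNA and from -0.01 to -0.0013 with both, without a call. Of 161 named gene calls 97 to 139 stayed without 1 array and 149 with trend and robust settings, 144 of the 145 tested stayed with array weights and 40 of the 86 tested with only the 6 arrays, and 0 turned. Quantile normalization kept 144 of 145 and the mean of probe sets all 145 but could test little, since the columns already shared 1 distribution and each gene had 1 probe set. Signal near the lower end limits what the Obp2a values can show. No paired analysis was possible because the groups share no replicate numbers.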

Other observations

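The comparison of TSC22D4 with LCN13 shRNA, its genes and lists, and the tests of the lipogenic and epididymal patterns were chosen after the data were seen.

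TSC22D4 shRNA compared directly with LCN13 shRNA is a difference of means without control arrays and with the same amount of control virus on each side, although the spread per gene was shared over all 12 arrays. Single genes higher with TSC22D4 shRNA, named after their values were seen, were Gys2 (1.74, SE 0.28, adjusted p = 0.036), Gbe1 (0.47), Gyg (0.33), Lss (0.77, adjusted p = 0.036) and Hsd17b7 (0.49). Olr1 (1.10, adjusted p = 0.0188), Nrg4 (0.57), Igkv4-70 (2.06), Igkv5-43 (1.83) and Igkv4-73 (1.79) were higher as well, and Samd9l (-0.51, adjusted p = 0.00483), Dpp4 (-0.59), Fads1 (-0.34), Map1b (-0.70) and the glutathione transferase genes Gstt1 (-0.83) and Gsta4 (-0.70) were lower. Apart from Samd9l, each of these genes lost its call without LCN13 replicate 5 or 6 or TSC22D4 replicate 10, with an adjusted p of up to 0.0727 for Olr1, 0.123 for Gys2, 0.126 for Lss and 0.171 for Nrg4. Camera called 11 lists, 9 higher and 2 lower, of which 0 held with an estimated correlation or with fry. De novo lipogenesis had a median of 0.35, with 14 higher and 2 lower when adjusted over the list alone and Fads1 the member that passed over all genes, on the lower side (camera adjusted p = 5.28e-06, adjusted p = 0.559 with an estimated correlation). Cholesterol synthesis had a median of 0.23, with 2 passing higher, 9 when adjusted over the list alone (camera adjusted p = 7.17e-06, adjusted p = 0.67 with an estimated correlation). The others, each with its median and camera adjusted p, were cell cycle (0.18, 8.38e-06), neutrophil markers (0.05, 0.000844), fatty acid oxidation (0.09, 0.00208), T and NK cell markers (0.07, 0.00298), the tricarboxylic acid cycle (0.11, 0.0165), oxidative phosphorylation (0.05, 0.0471) and extracellular matrix (0.11, 0.0471) on the higher side and liver markers (-0.13, 0.00208) on the lower, with adjusted p = 0.559 for neutrophil markers and adjusted p = 0.86 for the rest with an estimated correlation. In total 239 genes passed, 106 higher and 133 lower. The count was 2, 4 and 582 without LCN13 replicates 5, 6 and 8, 4, 6 and 8 without TSC22D4 replicates 10, 11 and 12, and 73 without combined-group replicate 13, and it was 319, 182 and 306 without control replicates 1, 2 and 3, so single arrays decide it. Mesothelial markers had a median of -0.38 in this comparison (camera adjusted p = 0.000169, adjusted p = 0.86 with an estimated correlation), with the high values in LCN13 replicates 5 and 6.

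Lipogenic genes were higher in the 6 arrays with TSC22D4 shRNA than in the 6 without, by 0.25 log2 of the list mean (exact two-sided permutation p = 0.00649 over 924 arrangements, adjusted p = 0.0487). Low control arrays as the whole cause are argued against, since TSC22D4 lay above LCN13 by 0.291 (SE 0.0714), although this difference by itself did not pass (exact two-sided permutation p = 0.1, the smallest that 20 arrangements can give, adjusted p = 0.224), and so is a larger share of adipocytes, since the adipocyte list moved by -0.0284. Genes of the list that move together between animals are counted once per array in the permutation test, so they do not inflate it, while TSC22D4 against control alone had adjusted p = 0.564 with an estimated correlation. As a hypothesis, found and tested on the same data, the TSC22D4 shRNA may raise lipogenic genes in fat. Feeding state and the choice of representative animals were not given and stay open.

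TSC22D4 replicate 11 held high levels of genes of the epididymis, the duct beside the testis around which much abdominal fat of male mice lies. Lcn8 was at 10.9 against a median of 5.97 in the 11 other arrays, Defb20 at 10.4, Lcn9 at 9.96 and Adam7 at 8.41. Among the 11 others Defb20 reached 7.81 (median 5.88) and Lcn8 6.72. The testis genes Prm2 and Prm1 reached 8.01 and 7.45 there (medians 6.27 and 6.42). Of 8 epididymal markers 4 lay at least 1 log2 above the others, with a median of 1.55, against 0 of 9 testis markers, with a median of -0.02. A piece of epididymis in that sample is a candidate source. Of the 17 genes on the list 3 are also on another list and 1 lay above the array median of 6.31 in the other arrays. No biological explanation was tested.

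Mesothelial markers lay above the 9 arrays of other groups by a median of 0.43 in LCN13 replicate 5 and 0.76 in replicate 6, and by -0.12 in replicate 8. None of the 15 is on another list, and 11 lay above the array median in other groups. Xist was at 5.79 to 5.83 and the Y-linked gene Eif2s3y at 10.0 to 10.5 on all 12 arrays.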
